A study of Mus musculus with 10 samples.

How the data were processed

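RNA was sequenced from sorted Oct4-negative somatic cells of gonads of single female Gulo-deficient embryos on a C57BL/6 background at embryonic day 13.5. Per the labels' protocols, 2 ng of total RNA per sample went into a low-input total RNA library kit. The samples were grouped by the treatment label into vitamin C supplied (n = 5) and vitamin C withdrawn (n = 5). The design text calls the replicates biological and the samples single embryos; whether embryos that share a number in their titles are litter mates is not stated, so p-values measure the spread between these samples only.

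The authors deposited 1 table of gene-level rlog values, which are on a log2 scale and shrink the values of weakly expressed genes towards their mean. Per the submitters' processing notes, the tools were Trim Galore 0.4.0, TopHat2 2.1.1 and DESeq2 1.20.1, with genome build mm9. The use of strand in counting is not given in the sources used here. Library depth cannot be read from rlog values, so the depth per sample is unknown, no counting interval is given and a count model was not used. Since the scale is shrunken, fold changes are understated, most for weakly expressed genes. The table held 13578 genes with values from 4.04 to 21.2, and sample medians between 9.12 and 9.14. All 10 columns matched a sample title, and no 2 samples had equal values (0% of genes).

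The choices that follow were made before the data were examined: the groups, the tests, the gene lists, the rule for named genes and the first set of other settings. Genes with a mean of at least 3 over all samples were to be tested, which removed 0 genes. Each gene was tested with limma 3.58.1 in R 4.3.3 (matrixStats 1.5.0), withdrawn against supplied, with a variance trend and no covariate, and Benjamini-Hochberg adjustment at 0.05. Of 35 gene lists, the 33 with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists. Beside it stood camera with an estimated correlation and fry for movement in 1 direction. Fry's test for change in either direction and an exact permutation test of the list means, two-sided, over 252 orders (smallest possible p 0.00794), were added later. The mitochondrially encoded list (0 of 15 members) and the list of Y-linked genes with Xist (1 of 5) had too few members and were not tested. The first 3 principal components of the gene-centred values were tested by exact permutation, two-sided.

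Named genes were the 12 largest rises and falls past the threshold or all where fewer passed. Where fewer than 5 passed in a direction, the 6 of smallest p in that direction were named too. Added to these were the 3 members of smallest p in each list described and 22 genes fixed in advance. Other genes named, such as Chgb, Fos, Ltf, Ngp, Lars2 and AW551984, were chosen after their values were seen. Some genes that the rule names are not reported here.

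Other settings tried were another mean minimum (5, or no filter), no variance trend, robust variance estimation, median centring, quantile normalization, sample weights, the replicate number as a block, averaging of samples that share a title number, the germ cell or erythroid list mean as a covariate, exact permutation of medians (smallest possible p 0.0476), the 500 genes of largest variance for the components, and leaving out each embryo in turn. Settings added after seeing the data were the immediate early list mean as a covariate, a mean minimum of 7, leaving out the 3 libraries of highest Fos, the title number as a random block, and components without Lars2 and Rn45s or without Chgb, Dgkk and Rgs4. To see how often other groupings give as much, 100 of the 126 splits of the samples into 5 and 5 were refitted with a fixed seed, and all 35 splits of the 8 samples left when embryos that share a title number are averaged.

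The tests were tried on simulated data for the withdrawn against supplied comparison of 13578 genes, with 50 genes moved by each size. Of those moved by 0.2, 54% were recovered, of those moved by 0.3, 86%, of those moved by 0.4, 100%, and of those moved by 0.5, 98%. Among the unmoved genes 9 were called. The 200 genes moved at once made the Benjamini-Hochberg cutoff easier to meet than in the real data, where 3 genes passed. The shares recovered therefore do not show how many real changes of these sizes would be found. A list moved by 0.1 had a camera adjusted p of 7.98e-08 and 0 of 32 unmoved lists were called. Each gene was drawn independently in these simulated data, whereas estimated correlations in the real lists reached 0.759 (ribosomal protein). The simulation therefore does not show that camera with its preset correlation holds its error rate in the real data.

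The reference annotation used here is GENCODE M21 with RefSeq names on GRCm38, another build than that of the table. It served only for gene types, newer symbols, overlaps, chromosomes and distances between genes (13496 genes had a position, 99.4%), and no coordinates are given. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.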

Results

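Gene expression was measured by RNA sequencing in gonadal somatic cells of single female mouse embryos at embryonic day 13.5. All embryos lacked Gulo, the enzyme of the last step of vitamin C synthesis, so that vitamin C reached them only through the maternal diet. The cells were the fraction left after sorting out cells that carry the germ cell factor Oct4. In 5 embryos vitamin C had been supplied and in 5 it had been withdrawn during early gestation, and the comparison asks which genes of the gonadal soma respond to its withdrawal. Expression was given as regularised log2 (rlog) values for 13578 genes, with sample medians between 9.12 and 9.14. The read depth behind these values is unknown, so no counting interval is given. Changes below are withdrawn minus supplied on the rlog (log2) scale, which shrinks the changes of weakly expressed genes most, and ± marks the SD over n = 5 embryos unless SE is written.

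Zfp783, Rps4y2 and 1700106J16Rik fell when vitamin C was withdrawn, and in each of them all 5 withdrawn embryos lay below all 5 supplied ones. Zfp783, a zinc finger gene of chromosome 6 that the reference annotation lists as a transcribed pseudogene, went from 8.76 ± 0.0947 to 8.26 ± 0.146. This is a change of -0.50 (SE 0.0658, limma adjusted p = 0.0110), or 0.707-fold on the rlog scale. Rps4y2, despite its name a processed pseudogene of chromosome 6 related to the ribosomal protein gene Rps4x, went from 9.97 ± 0.160 to 9.57 ± 0.0588, a change of -0.41 (SE 0.0644, limma adjusted p = 0.0394). The weakly expressed 1700106J16Rik, a coiled-coil protein gene now named Ccdc182, went from 5.83 ± 0.0736 to 5.61 ± 0.0318, a change of -0.22 (SE 0.0334, limma adjusted p = 0.0288). Zfp783 overlaps Zfp956 on the same strand (Zfp956 -0.080, limma adjusted p = 0.963) and Rps4y2 lies opposite Tmtc1 (Tmtc1 0.17, limma adjusted p = 0.900), and reads of Rps4y2 can also be shared with Rps4x (0.086, limma adjusted p = 0.963), so both values are uncertain.

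By limma, 3 of the 13578 genes fell and 0 rose at an adjusted p under 0.05. At an unadjusted p under 0.05, 333 genes were higher and 386 lower in the withdrawn embryos, 719 in all where chance gives 679. Per-gene exact permutation of the difference of medians cannot decide here. Its smallest possible p with 5 embryos in each group is 0.0476, 12932 genes would have to reach it before any could pass, and 700 did, so its count of 0 is set by the design. Groups did not overlap in 110 genes, against 108 by chance (0.794% of genes). Over all genes the median residual SD was 0.0730. Without supplied embryo 1 or without withdrawn embryo 5 the count was 0, and it was 1 without withdrawn embryo 2 or withdrawn embryo 4. Zfp783 stayed past the threshold in 22 of 24 other settings that could change a call; its limma adjusted p was 0.0642 without supplied embryo 1 and 0.0504 without withdrawn embryo 5. Rps4y2 stayed past it in 6 of 24 settings, and of the embryos left out in turn only supplied embryo 5 left its call standing (limma adjusted p between 0.0510 and 0.163 without any of the others), while 1700106J16Rik stayed past it in 13 of 23 settings and lost its call without supplied embryos 1, 2 or 3 or withdrawn embryos 1, 2, 4 or 5 (limma adjusted p between 0.0516 and 0.146). Embryos 2 and 3 of each group share the first number of their titles, and with such embryos averaged Rps4y2 and 1700106J16Rik lost their calls (limma adjusted p = 0.154 and 0.0817). With the title number as a random block (consensus correlation 0.238), 2 genes passed and Rps4y2 did not (limma adjusted p = 0.0720).

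**Figure D1:**
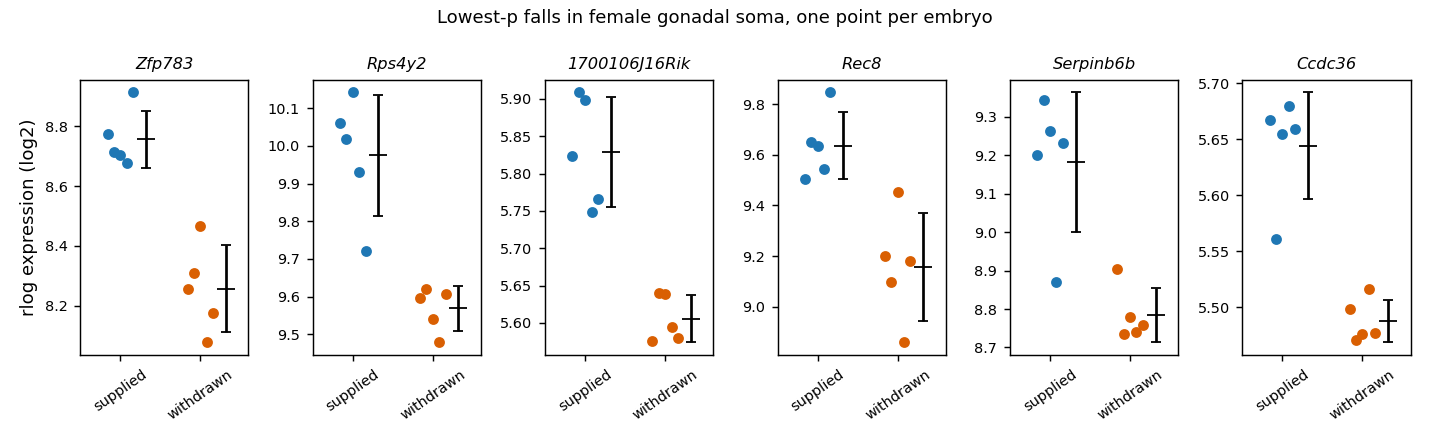
Expression (rlog, log2 units) of Zfp783, Rps4y2, 1700106J16Rik, Rec8, Serpinb6b and Ccdc36, with 1 point per embryo, supplied in blue and withdrawn in orange; black bars are the mean and SD of 5 embryos, and each panel has its own axis, which does not start at 0. Groups are apart in all panels but that of Serpinb6b, where supplied embryo 4 (8.87) lies below withdrawn embryo 1 (8.91); Rec8, Serpinb6b and Ccdc36 are short of the threshold.

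Rec8 and Ccdc36, genes of meiosis, and Serpinb6b were among the genes of smallest p on the lower side, short of the threshold. Rec8, a meiotic cohesin subunit, was at 9.64 ± 0.133 in supplied and 9.16 ± 0.214 in withdrawn embryos (change -0.48, SE 0.0863, limma adjusted p = 0.0654). Ccdc36, now named Iho1 and required for meiotic DNA breaks, changed by -0.16 (SE 0.0266, limma adjusted p = 0.0638). Serpinb6b, a serine protease inhibitor, was at -0.40, the axonemal dynein gene Dnahc8 at -0.20 and A730017C20Rik at -0.17, each with a limma adjusted p of 0.0654. In the other direction the 6 smallest p-values, also short of the threshold, belonged to the sodium channel subunit Scn2b (0.23, limma adjusted p = 0.289), Prdm11 (0.21) and Zfhx4 (0.17, both limma adjusted p = 0.518), the WNT antagonist Sfrp1 (0.19) and the adhesion gene Sdk2 (0.21, both limma adjusted p = 0.524), and Gosr2 (0.15, limma adjusted p = 0.594).

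The genes of vitamin C handling, DNA demethylation and ovarian identity that were named in advance did not pass the test. Of 22 such genes, 15 were tested and 0 passed by limma, with 1 of them, Tet1, at an unadjusted p under 0.05. Gulo, Amh, Pou5f1, Ddx4, Dazl, Stra8 and Sycp3 have no row under these symbols among the 13578 genes, so they could not be tested. Tet1, a DNA demethylase that uses vitamin C, was at 10.98 ± 0.103 and 11.11 ± 0.111, a change of 0.13 with a 95% interval from 0.0016 to 0.25 (limma adjusted p = 0.931). Tet2 differed by 0.040 and Tet3 by 0.054, and the maintenance methyltransferase Dnmt1 by 0.0011. The vitamin C transporter Slc23a2 differed by -0.044. Among regulators of the ovarian supporting cells, Foxl2 differed by -0.069, Wnt4 by 0.011, Rspo1 by 0.0064 and Bmp2 by -0.096, and the gonadal regulators Nr5a1 and Sox9 by -0.041 and -0.045. The prolyl hydroxylase P4ha1 differed by -0.041, Vegfa by 0.00093, Col1a1 by 0.14 and Xist by 0.16. The intervals of these 15 genes reached at most 0.405 from 0, the upper end for Xist.

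With camera's preset correlation the stromal, collagen and ribosomal protein lists passed upwards and the endothelial, neural and mesonephric lists downwards, and none of the 6 passed with an estimated correlation. In the stromal list 21 of 25 members were above 0, with a median of 0.077, led by Dcn (0.24), Col3a1 (0.19) and the receptor Pdgfra (0.15), and the list rose by camera (adjusted p = 0.00077; adjusted p = 0.92 with an estimated correlation). The list of collagen and matrix assembly, which shares Col3a1, Col1a1 and Col1a2 with it, rose with 25 of 31 members above 0 and a median of 0.070 (adjusted p = 0.0133; adjusted p = 0.92 with an estimated correlation). Col14a1 was at 0.16 and Col3a1 at 0.19, whereas Col2a1, the collagen of cartilage, was at -0.21. The ribosomal protein list rose with 29 of 37 members above 0 and a median of 0.024, Rps25 (0.12), Rpl38 (0.098) and Rps16 (0.12) first (adjusted p = 0.0207; adjusted p = 0.92 with an estimated correlation). That direction rested on withdrawn embryo 1, whose list mean was 13.235 against 12.98 to 13.04 in the other withdrawn embryos, and without it the mean change was -0.0155 (adjusted p = 0.510). The call also ended with quantile normalization (mean change 0.0088, adjusted p = 0.587), sample weights (0.010, adjusted p = 0.365) and the germ cell covariate (0.0098, adjusted p = 0.471).

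The endothelial list fell, with 18 of 24 members below 0 and a median of -0.033 (camera adjusted p = 0.0048; adjusted p = 0.92 with an estimated correlation). Eng, the TGF-beta co-receptor endoglin, fell when adjusted over the list alone (-0.39, SE 0.0821, limma adjusted p = 0.0050), and was not past the threshold over all genes (limma adjusted p = 0.21). Ramp2 was at -0.20 and Ecscr at -0.082. The neural and glial list fell with 12 of 14 members below 0 and a median of -0.078 (camera adjusted p = 0.0133; adjusted p = 0.92 with an estimated correlation), with the neurofilament gene Nefm at -0.48, Hand2 at -0.25 and the receptor Ret at -0.13. Supplied embryos 2 and 3 held the most Nefm, at 10.10 and 9.42, against 8.18 to 8.57 in the other 8 embryos. The list of mesonephros and duct epithelium fell with 16 of 21 members below 0 and a median of -0.057 (camera adjusted p = 0.0299; adjusted p = 0.92 with an estimated correlation), and held Krt8 at -0.14, Ret at -0.13 and Cldn6 at -0.10.

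In all, 33 lists were tested and 6 passed camera with its preset correlation, 3 in each direction. With an estimated correlation 0 passed and by fry for movement in 1 direction 0, each with 0 lists also at an unadjusted p under 0.05 (camera with its preset correlation had 8). Exact permutation of the list means, whose smallest possible p is 0.00794, can pass only 6 or more lists together, and 0 lists had an unadjusted p under 0.05 by it. Of 671 list members, 0 passed over all genes by limma, with 51 at an unadjusted limma p under 0.05, and members of 7 lists did when adjusted over the list alone. That last adjustment was made within each list and not over the 33 lists. The stromal call held without any 1 embryo. The endothelial mean change of -0.057 became -0.035 without supplied embryo 4 and -0.031 without withdrawn embryo 1, and the call was lost (adjusted p = 0.154 and 0.182), as it was without the 3 libraries of highest Fos (-0.045, adjusted p = 0.0798). The neural call was lost without supplied embryo 2 (mean change -0.023, adjusted p = 0.716) or supplied embryo 3 (adjusted p = 0.0676). These are the supplied embryos that share a title number, and their deviations from the group mean correlated at 0.138, against a median of -0.258 over the pairs of supplied embryos, as those of withdrawn embryos 2 and 3 did at 0.000028 against -0.293. With embryos that share a title number averaged, the neural call (mean change -0.053, adjusted p = 0.277) and the collagen call (mean change 0.013, adjusted p = 0.486) were lost. The collagen call (mean change 0.043) was lost without supplied embryos 2, 3 or 5 or withdrawn embryo 2 (mean changes 0.014, 0.034, 0.034 and 0.028, adjusted p = 0.464, 0.0863, 0.167 and 0.198). The mesonephros call (mean change -0.050) was lost without supplied embryos 3, 4 or 5 or withdrawn embryos 1 or 3 (mean changes -0.046, -0.036, -0.048, -0.040 and -0.026, adjusted p = 0.0870, 0.195, 0.0682, 0.179 and 0.423) and without the 3 libraries of highest Fos (-0.013, adjusted p = 0.931). The ribosomal protein call (mean change 0.030) was lost without supplied embryos 4 or 5 (mean changes 0.018 and 0.0016, adjusted p = 0.167 and 0.787). Quantile normalization also ended the collagen and mesonephros calls (mean changes 0.022 and -0.043, adjusted p = 0.351 and 0.101), sample weights and the erythroid covariate the mesonephros call (mean changes -0.045 and -0.044, adjusted p = 0.0842 and 0.0724), and the germ cell covariate the endothelial and mesonephros calls (mean changes -0.031 and -0.025, adjusted p = 0.196 and 0.577). At a mean minimum of 7, with fewer genes tested, the neural call was lost (adjusted p = 0.203) although the mean change was no smaller (-0.12, against -0.11 over all its members). Without withdrawn embryo 5, 15 lists passed.

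**Figure D2:**
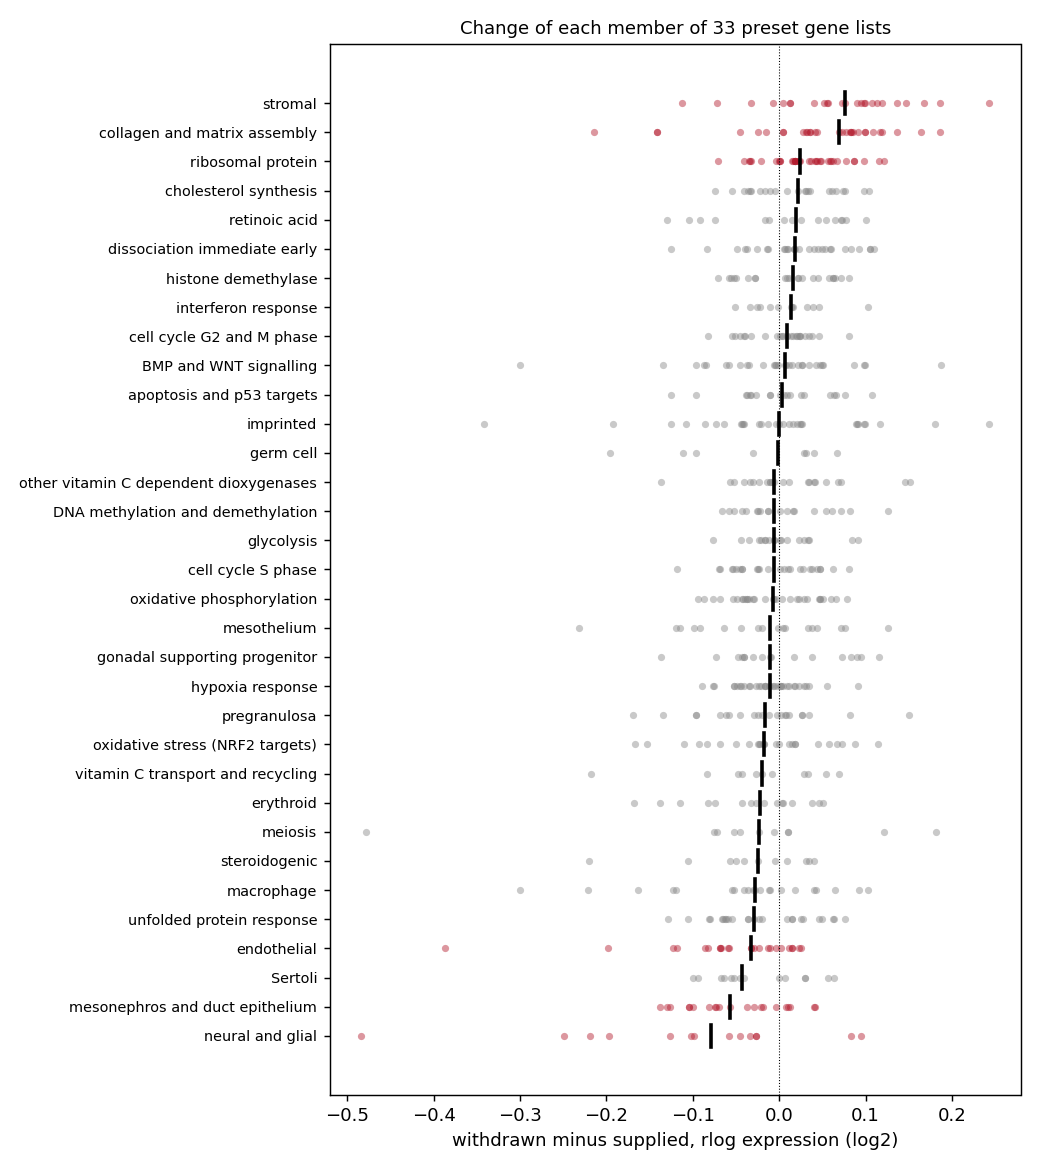
Change of each tested member (withdrawn minus supplied, rlog log2 units) of 33 gene lists, with 1 point per gene and a black tick at the list median; lists that passed camera with a preset correlation are red. List medians lie between -0.078 (neural and glial) and 0.077 (stromal).

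Of the meiosis genes, Rec8 carried the call of the list, whose members did not share a direction. Of 11 tested members of the meiosis list, Rec8 (-0.48) and the recombinase Dmc1 (-0.072) fell when adjusted over the list alone (limma adjusted p = 0.00042 and 0.0217), and 0 members passed over all genes by limma, where 4 had an unadjusted p under 0.05. Stag3, another meiotic cohesin subunit, was at 0.18 and did not pass (limma adjusted p = 0.0606 over the list alone). The list changed by fry's test for change in either direction (adjusted p = 0.0058), the 1 list of 33 to do so, and not by its test for 1 direction (adjusted p = 0.944) or by camera (adjusted p = 0.0872). Without Rec8 the adjusted p of the first test was 0.115, so the call rests on that gene, and without supplied embryo 4 it was 0.0507. In the germ cell list, of which 8 of 30 members were tested, Tdrd1, a gene of the piRNA pathway, fell when adjusted over the list alone (-0.20, limma adjusted p = 0.0011; 0.167 over all genes). Tfap2c was at 0.067 and Nanos3 at 0.028, and the list median was -0.0012 (camera adjusted p = 0.627).

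The supporting cell lists did not pass camera. Pregranulosa genes had a median of -0.016 over 22 members (adjusted p = 0.627), with Irx5 at 0.15 and Runx1 at -0.097. Sertoli genes had a median of -0.043 over 14 members (adjusted p = 0.195), with Fgf9 at -0.10 and Aard at -0.067, and Vnn1 (-0.095) fell when adjusted over the list alone. Vnn1 did not pass over all genes (limma adjusted p = 0.594). Genes of the gonadal supporting progenitor had a median of -0.011 (adjusted p = 0.731), with Igf1r at 0.12, Gadd45g at -0.14 and Zfpm2 at 0.083. The steroidogenic list had a median of -0.024 (adjusted p = 0.234), with Akr1cl at -0.22, Star at -0.11 and Mc2r at -0.024. Among the mesothelium genes (median -0.010, adjusted p = 0.376), the keratin gene Krt7 fell when adjusted over the list alone (-0.23, SE 0.0504), beside Krt14 at -0.091 and Igfbp5 at 0.13. Krt7 did not pass over all genes (limma adjusted p = 0.239). Macrophage genes had a median of -0.028 (adjusted p = 0.234), with Lyz2 (highest in supplied embryo 3, at 7.93) at -0.30, Itgam at -0.22 and Ptprc at -0.12. Erythroid genes had a median of -0.022 (adjusted p = 0.627), with Epb4.2 at -0.14, Hemgn at -0.082 and Epor at -0.032.

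None of the lists of vitamin C handling, of gene groups with members that use it, or of hypoxia, glycolysis and oxidative stress passed camera. The list of vitamin C transport and recycling had a median of -0.020 (adjusted p = 0.627), with Cyb561 at -0.22, Txnrd1 at -0.084 and Gsto1 at 0.069. Genes of DNA methylation and demethylation had a median of -0.0056 over 20 members (adjusted p = 0.811), where Dnmt3a was at 0.072. Histone demethylase genes had a median of 0.016 (adjusted p = 0.627), with Kdm3b at 0.081, Kdm1b at 0.071 and Phf8 at 0.062. In the list of other dioxygenases (median -0.0056, adjusted p = 0.717), the collagen hydroxylase genes P4ha3, Leprel1 and Plod1 were at -0.14, 0.15 and 0.15. The hypoxia response had a median of -0.011 (adjusted p = 0.627), with Tpi1 at 0.092, Bhlhe40 at -0.076 and Pfkp at -0.077, and glycolysis -0.0059 (adjusted p = 0.745), where Pfkm was at 0.085 beside Tpi1 and Pfkp. In the oxidative stress list of NRF2 targets (median -0.018, adjusted p = 0.539), the cystine transporter Slc7a11 fell when adjusted over the list alone (-0.17, SE 0.0381), beside Me1 at -0.15 and Abcc1 at -0.093. Over all genes Slc7a11 did not pass (limma adjusted p = 0.281).

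Lists of general cell functions did not pass either. The unfolded protein response had a median of -0.029 (adjusted p = 0.195), with Pdia4 at -0.13, Dnajb11 at -0.11 and Ddit3 at -0.080. Cholesterol synthesis had a median of 0.022 (adjusted p = 0.442), with Lss at 0.099, Dhcr7 at 0.10 and Sqle at 0.073. S phase genes had a median of -0.0060 (adjusted p = 0.722; Ccne2 -0.070, Tyms -0.069), and genes of G2 and M phase 0.0091 (adjusted p = 0.945; Ccnb2 0.081, Ube2c -0.082, Cdc25c -0.045). Retinoic acid genes had a median of 0.020 (adjusted p = 0.711), with Rxra at 0.10 and Stra6 at 0.073. In BMP and WNT signalling (median 0.0064, adjusted p = 0.843) Sfrp1 rose when adjusted over the list alone (limma adjusted p = 0.524 over all genes), whereas Sfrp2 was at -0.30 and Id4 at -0.085. Imprinted genes had a median of -0.00061 (adjusted p = 0.731), with Dcn at 0.24, Plagl1 at 0.18 and Zrsr1 at -0.11. Oxidative phosphorylation had a median of -0.0072 (adjusted p = 0.731; Atp5o -0.094, Ndufs3 0.065, Sdhc 0.078), apoptosis and p53 targets 0.0031 (adjusted p = 0.731; Sesn1 0.11, Mdm2 -0.096, Tnfrsf10b 0.076), and the interferon response 0.013 (adjusted p = 0.731; Irf9 0.10, Ifit2 -0.052, Irf7 -0.026). The immediate early genes of tissue dissociation had a median of 0.018 (adjusted p = 0.627), with Klf6 at 0.11, Hspa1a at 0.045 and Egr3 at 0.11. Median, mean and camera direction differed in sign for 6 lists, namely other dioxygenases, imprinted, supporting progenitor, glycolysis, DNA methylation, and BMP and WNT signalling.

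The largest differences between embryos did not follow the vitamin C supply. The first principal component held 30.3% of the variance, of which 5.52% lay between the groups (exact permutation p = 0.508, two-sided, adjusted p = 0.730 over 3 components), and it set Fosb, Fos and Egr1 against Chgb, Dgkk and Rgs4. Fos was highest in supplied embryo 4 (12.59), withdrawn embryo 3 (12.50) and withdrawn embryo 2 (11.70).

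Chgb, a granule protein of neuroendocrine cells, was at 8.36, 12.42 and 10.76 in supplied embryos 1, 2 and 3 and between 6.82 and 7.10 in the other 7 embryos, and Dgkk and Rgs4 were also highest in supplied embryos 2 and 3. The neutrophil genes Ltf and Ngp were highest in supplied embryos 1, 2 and 3 and withdrawn embryo 5, with Ltf between 8.32 and 9.34 there and between 7.31 and 7.70 in the other 6. The second component held 13.3% of the variance, 49.96% of it between the groups (exact permutation p = 0.0159, two-sided, adjusted p = 0.0476). With Chgb, Dgkk and Rgs4 left out that share was 0.739% (adjusted p = 0.825), and without any 1 embryo other than supplied embryo 1 the adjusted p lay between 0.0952 and 0.274. Components were recomputed and ranked anew in these fits, so the second need not be the same axis, and the low share need not mean that the separation rested on these genes. The third component held 11.9% of the variance (exact permutation p = 0.730).

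**Figure D3:**
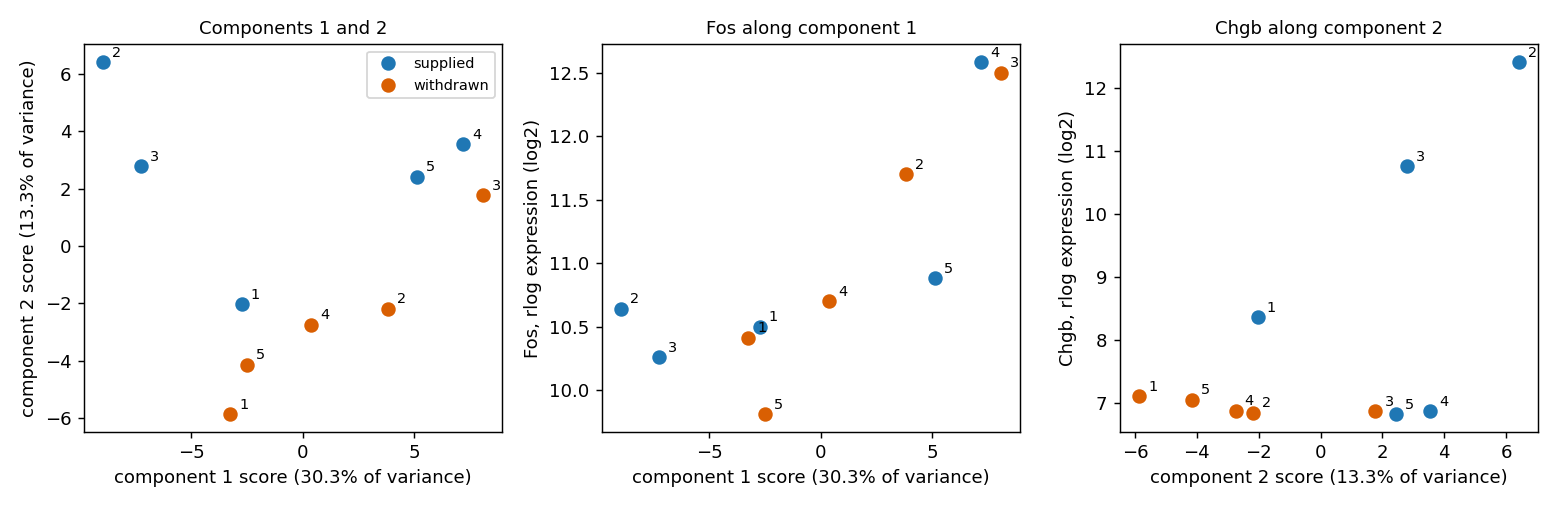
Scores of the 10 embryos (supplied in blue, withdrawn in orange, numbered by replicate) on components 1 and 2, Fos expression along component 1 and Chgb expression along component 2 (rlog, log2 units). Fos is highest at the positive end of component 1, in supplied embryo 4 (12.59) and withdrawn embryo 3 (12.50), and Chgb reaches 12.42 in supplied embryo 2.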

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

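Of the tests in this part, those of the splits with averaged embryos, of the neighbours of Zfp783, of the stromal share, of the meiosis list and with the immediate early covariate were chosen only after the result was seen; the test with an estimated correlation was set beforehand and only read as an explanation afterwards. A single embryo stood far from the other 4 of its group in 14 of 168 groups of values checked, where chance gives about 8.4. Among genes these were Scn2b in withdrawn embryo 3 (8.62, others 8.77 to 8.79), Sdk2 in supplied embryo 4 (11.34, others 11.07 to 11.15), Ccdc36 in supplied embryo 2 (5.56, others 5.65 to 5.68), Serpinb6b in withdrawn embryo 1 (8.91, others 8.73 to 8.78), Xist in withdrawn embryo 3 (15.21, others 14.68 to 14.79) and Rps16 in withdrawn embryo 1 (12.44, others 12.14 to 12.22). Withdrawn embryo 1 also stood apart in the list means of endothelial genes (8.42, others 8.53 to 8.57), DNA methylation genes (10.34, others 10.42 to 10.43) and ribosomal protein genes (13.235, others 12.98 to 13.04). Other list means that stood apart were those of supporting progenitor genes in withdrawn embryo 4 (11.01), erythroid genes in withdrawn embryo 5 (8.90), apoptosis and p53 targets in withdrawn embryo 3 (9.12), unfolded protein response genes in supplied embryo 5 (10.565) and immediate early genes in supplied embryo 4 (9.885).

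The fall of Zfp783, Rps4y2 and 1700106J16Rik was met by as many calls in 2 of 100 splits of the embryos, the real one included, which argues against a chance split where all embryos count as independent (the highest other, with 275 genes against 3, parted supplied embryos 1, 2 and 3 and withdrawn embryos 1 and 5 from the rest, a structure along the first component). With embryos that share a title number averaged, Zfp783 alone passed, and 4 of 35 splits gave as many calls as this 1 (highest other 28), so chance could not be excluded there. For a dissociation response, the mean of the immediate early list hardly differed between the groups (9.27 ± 0.349 and 9.29 ± 0.378). With it as a covariate a median of 99.7% of the fall was left, and Zfp783, Rps4y2 and 1700106J16Rik all stayed past the threshold (limma adjusted p = 0.00238, 0.0137 and 0.0136). A covariate that differs so little between the groups could remove hardly any of the fall, so this fit cannot decide on that cause. The near-equal means gave no sign of it, as far as the immediate early list measures it. A response outside that list was not tested. Linked strain haplotypes stay open. The 50 genes of smallest p, most of them not called, held 2 pairs within 5 Mb against a median of 7 in random draws. Zfp783, however, has a neighbour within 1 Mb, Gimap9 (-0.21), at an unadjusted limma p under 0.001. Germ cells left by the sort also remain open. With the germ cell covariate a median of 102% of the fall was left, while the call of Rps4y2 ended as its error widened (from -0.41, SE 0.0644, to -0.40, SE 0.0690, limma adjusted p = 0.0767). That covariate is the mean of the 8 of 30 listed members that were tested, some weakly expressed (Nanos3 at 4.40 in supplied embryos), so it may measure germ cells poorly. Pou5f1, Ddx4 and Dazl are not among the 8. A strain variant at a single gene, reads shared with Rps4x or Zfp956, and vitamin C supply itself were not tested.

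The 6 lists that passed camera with a preset correlation were matched or exceeded in 74 of 100 splits (highest other 16), so chance could not be excluded. With an estimated correlation 0 lists passed, which is what correlation between the genes of a list that the preset does not allow for would give. A larger stromal share may also lie behind the lists: the medians of the 10 other cell type lists were all below 0, from -0.078 to -0.0012. This stays open, since the mean of the stromal list, higher by 0.071, did not pass by itself (exact permutation p = 0.159).

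The meiosis list had the smallest p of the 33 lists for change in either direction (0.000175), and the smallest p over the lists was as small in 10 of 100 splits (smallest of the others 2.04e-06), so chance could not be excluded. Fewer germ cells left by the sort in the withdrawn samples would lower the members together. The directional test of limma's fry gave an unadjusted p of 0.190, and Stag3 was at 0.18 without passing, so that explanation remains open. The call for either direction ended without Rec8 (adjusted p = 0.115, unadjusted 0.00603) and held without any other member. Over the embryos left out in turn its adjusted p ranged from 0.000168 to 0.0507, the highest without supplied embryo 4.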

How the results depend on the processing

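Of the settings in this part, the immediate early covariate, the mean minimum of 7, the 3 libraries of highest Fos left out, the title number as a random block and the components without named genes were chosen only after the result was seen. The filter at a mean of 3 removed 0 genes, so the setting without it tests nothing. The count of 3 changed genes, all lower, became 1 with no variance trend, quantile normalization, averaging over title numbers or a mean minimum of 7, 5 with robust variances or sample weights, and 0 with exact permutation of medians, where the design allows no other count below 12932. With the immediate early covariate it was 12, of which 11 fell and 1 rose. Leaving out each embryo in turn gave 0 to 4 changed genes, 0 to 4 that fell and 0 to 0 that rose. The 6 lists became 3 with the germ cell covariate, 4 with quantile normalization or sample weights, 0 with an estimated correlation and 0 by fry, and 4 to 15 with an embryo left out. The mean change of the ribosomal protein list ranged from -0.0155 (without withdrawn embryo 1) to 0.0501 with an embryo left out. The share of the second component between the groups (49.96%) lost its call with median centring (49.2%), quantile normalization (41.7%) and the 500 genes of largest variance (25.9%). The call was also lost with averaging over title numbers (0.739%), the 3 libraries of highest Fos left out (22.5%) and Chgb, Dgkk and Rgs4 left out (0.739%). With averaging or with those libraries left out, too few orders of the samples remain for a single component to pass. Both of these losses were therefore set by the design. Components were recomputed and ranked anew in each setting, so the second need not be the same axis throughout. The second component's share ranged from 32.6% to 69.0% with an embryo left out, and that of the first from 0.00817% to 23.0%. Fewer samples or genes lower what leaving out and the higher minimum can call; for the other settings the cause was not tested.

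With the replicate block, 2 genes changed, 0 of them upwards, and 6 lists passed. Embryos with the same replicate number deviated with correlations of -0.364 to 0.172 in 5 pairs, and 1 embryo correlated best with its own number. These values showed no pairing by number, but so few pairs cannot exclude one. Of the other values, in the settings that could change a call, 2944 kept their side of the threshold, of which 37, all of genes short of it, differed in sign from the value reported (Vegfa 12, Dnmt1 8, Wnt4 7, Rspo1 6, Egr3 3, Sox9 1). Of the rest, 71 lost their call, 25 gained one and 1, the ribosomal protein list, changed direction. The depth of the libraries is unknown and limits weakly expressed genes such as 1700106J16Rik, whose changes the rlog scale shrinks.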

Other observations

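Of the tests in this part, those of the excess of falls, of germline genes, of neighbouring genes, of Lars2 and Rn45s, and of the immediate early covariate genes were chosen only after the result was seen, except that the split count of the last was stated beforehand. The row named Lars2, after a mitochondrial leucyl-tRNA synthetase gene, was the second highest of the table after the ribosomal RNA row Rn45s. It was at 19.26 ± 0.249 in supplied and 19.68 ± 0.202 in withdrawn embryos (change 0.42, exact permutation p = 0.0238, limma adjusted p = 0.865). Whether the reads of the Lars2 row come from the synthetase transcript was not tested, so the change is that of the row only. Rn45s differed by -0.010 (exact permutation p = 0.968). With the mean of the immediate early list as a covariate, 12 genes passed by limma. Besides Zfp783, Rps4y2 and 1700106J16Rik, the falls were Serpinb6b (-0.39), Rec8 (-0.48), Ccdc36 (-0.16), Eng (-0.39), Dnahc8 (-0.20), Tdrd1 (-0.20), the transferrin gene Trf (-0.27) and Slfn9 (-0.34), and AW551984 rose (0.25, limma adjusted p = 0.0448). As many genes passed with that covariate in 2 of 100 splits, the real one included (highest other 16). The covariate was chosen after the data were seen and hardly differed between the real groups, while it takes signal from splits that follow it. The split with 275 genes in the main fit had 1 with the covariate. The count therefore cannot decide on a chance split.

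At an unadjusted p under 0.001, 23 genes were lower and 2 higher in the withdrawn embryos, where chance gives 13.6 in all. An excess of 21 in 1 direction was met in 5 of 100 splits (highest other 64), so chance could not be excluded. Among the 23 genes were 2 of the 19 tested members of the germ cell and meiosis lists, Rec8 and Tdrd1, which were seen there before these lists were joined. The other 17 members had a median of -0.0058, with 9 below 0 (exact signed-rank p = 0.712). Zfp783 has 27 tested neighbours within 1 Mb, of which 0 passed by limma, 2 had an unadjusted p under 0.05 and 1 of them, Gimap9 (-0.21, limma adjusted p = 0.281), one under 0.001.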
